A study of Mus musculus with 6 samples.

How the data were processed

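The series holds 6 single-cell RNA libraries of dorsolateral and flank skin of mouse embryos, made with a droplet method that reads the 3′ end of transcripts. Groups came from the labels: E13.5 control (n = 2), E14.5 control (n = 2), E13.5 LOF (n = 1) and E14.5 LOF (n = 1). Each library was made from skin pooled over embryos, dissociated and sorted for cells that exclude DAPI, and sequenced on an Illumina HiSeq. A library is the unit of replication, and embryos within a pool cannot be told apart. The deposited matrices hold raw counts of UMIs per gene and cell barcode, whole numbers that no normalization step had changed. Per the submitters' processing notes the reads were processed with Cell Ranger and Seurat against mm10 (GRCm38), with no versions given. The smallest UMI total of a barcode ranged from 2568 to 3971 between libraries, so barcodes had been selected as cells before deposit, by a rule the labels do not give. The matrices hold 28000 genes, with rows for eGFP and tdTomato appended.

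Barcodes with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs were kept, which left 40653 of 41594. Kept cells numbered 6970 and 6028 in E13.5 control replicates 1 and 2, 6263 and 5850 in E14.5 control replicates 1 and 2, 6620 in E13.5 LOF and 8922 in E14.5 LOF. Median UMIs per barcode were 10882, 8469.5, 11064, 7980, 11234.5 and 8518 in the same order. For a share of 0, 3 over the number of cells was used as the floor, which bounds detection at this depth and not expression. Doublets were scored per library from simulated pairs of cells, and the highest scores were removed at a rate of 0.8% per 1000 cells, which took 4.68% to 7.14% of cells and left 38397. Counts were scaled to 10000 per cell and log transformed, 2000 variable genes gave 30 principal components, and a graph of 15 neighbours was split by the Leiden method at resolution 1 with seed 1, without any batch correction. Clusters were named from marker lists by their leading genes, compared with other clusters after adding 20 CPM, and those that met no marker list were left unnamed. Cell counts given for numbered clusters include cells called doublets. Dermal cells were clustered again at resolution 0.5 to find condensate-like cells. Placode-like and suprabasal-like cells were whole clusters of the first round, a departure from the plan to cluster keratinocytes again. Tools were Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

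UMI counts were summed per library over the cells of a class. The edgeR quasi-likelihood test (robust, TMM factors, filterByExpr) compared stages in the 4 control libraries and genotypes in all 6 libraries with stage as a covariate. P-values were adjusted by Benjamini-Hochberg over the genes tested, and an adjusted p under 0.05 counted as past the test. All adjusted p of genes are from edgeR unless DESeq2 is named. With 1 LOF library per stage, effects within a stage are values with no test. SE of a log2 fold change was derived from the fold change and its F statistic. Of the other classes, endothelial-like, macrophage-like, Schwann-like and muscle-like cells were planned for the same tests if every library held at least 20 cells, which all 4 did. Pericyte-like and mast-like cells also met that minimum but were not in the plan and were not tested. Shares of cells have exact binomial intervals, at 95%. For shares of cells with a UMI of Sox2, Sox18, Foxd1, Edar, Shh or Dkk4, each cell was thinned to 3000 UMIs. Sp5, Lef1 and Axin2 were not in that plan and were reported after the data were seen.

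Gene lists were tested with camera in limma on the same sums at a preset correlation of 0.01, adjusted over the lists of the class and comparison, and again with a correlation estimated from the residuals. No call at the preset correlation held with the estimated one in any of the 4 comparisons. The 17 lists were Wnt targets, dermal condensate, lower dermis and fascia, hedgehog, FGF and BMP response, matrix, proliferation, fetal growth, stress, hypoxia and glycolysis, tendon and cartilage, placode, basal epidermis, stratification, periderm and haemoglobin genes. Of these, 13 were tested in dermal cells and 12 in keratinocytes. Ptch1 is in the condensate and hedgehog lists, Sox9 in the tendon and cartilage and placode lists. Medians over a list within a stage used 1 CPM added to each value and were compared with 10000 random lists drawn from 20 bins of expression.

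Genes were named by a rule. Ctnnb1 came first. For each comparison in dermal cells and keratinocytes up to 10 rises and 10 falls followed, the largest among genes past the test with a mean log2 CPM of at least 5 and the same direction in every library. Their CPM in the class had to reach 1 part in 5 of the highest of any named class, as a guard against free RNA. Predicted genes, ribosomal protein, mitochondrial, haemoglobin, pseudogene and sex-linked marker genes were left out. Up to 4 members of each list with the smallest p were added, and 3 rises and 3 falls in the other classes. Where edgeR called no dermal gene, the same rule was applied, after the data were seen, to the fit with inferred batch of 3 levels. Groups, comparisons, tests, lists, markers and this rule were fixed before the data were examined. Positions are from GENCODE release M21 on GRCm38.

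The labels name no library batch. Batches were inferred after the data were seen, first as 2 levels, with E14.5 control replicate 1 and E14.5 LOF against the other 4 libraries, and then as 3 levels of 2 libraries each. The larger batch of the first coding holds both E13.5 controls, E14.5 control replicate 2 and E13.5 LOF. Both codings were fitted as a covariate, for genes and for lists. With 3 levels the genotype effect rests on 2 pairs of libraries and the stage effect on replicate 2 of the controls, with 1 residual degree of freedom. In dermal cells 5100 of 15161 genes passed 0.05 for the 3-level batch terms, and in keratinocytes 5433 of 13619. Across genes, which are not independent replicates, the log2 CPM of dermal cells correlated at r = 0.982 between E14.5 control replicate 1 and E14.5 LOF and at 0.919 between the E14.5 controls. Replicate numbers were checked as pairs. The difference between replicates 1 and 2 at E13.5 correlated with that at E14.5 across genes at r = 0.401 in dermal cells and 0.391 in keratinocytes, so a replicate block was fitted as an alternative. Between 45 and 103 barcodes were shared by any pair of libraries.

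Tests were tried on simulated data with the spread of the real libraries and 50 genes changed by each of 2, 4, 8 and 16 times. Simulated genes varied independently of each other and had no batch difference, so calls in the real libraries can be fewer and false calls more. The dermal genotype test called 10, 43, 49 and 50 of these, with 14 false calls over 14300 genes. The dermal stage test called 1, 40, 45 and 49, with 13 false calls over 13820 genes. In keratinocytes the stage test called 6, 37, 50 and 49 (17 false over 12562) and the genotype test 13, 47, 49 and 50 (20 false over 12846). With the 3-level batch the dermal test called 41, 50, 50 and 50, with 74 false calls over 14721 genes, and the keratinocyte test 48, 50, 50 and 50 (39 false over 13174). A simulated list of 12 changed members had a camera p of 1.96e-11 in the dermal genotype design, and 1 with no changed member a p of 0.0231, so a list p near 0.05 can arise with no change.

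Alternatives were DESeq2 with its own size factors, RLE factors in edgeR, no filter on low counts, doublets kept, class sums thinned to the smallest library, Leiden resolution 0.5, sub-cluster resolution 1, a replicate block, all 6 libraries for the stage comparison, each library left out in turn, and an estimated correlation for lists. Cells of at least 5000 UMIs, dermal cells without the condensate-like sub-cluster, the batch covariates and the 4 libraries of the larger batch were added after the data were seen. Where a left-out library leaves 1 sample in a group, that sample is assumed to vary like the others. Transcripts of eGFP and tdTomato were set aside from the comparisons.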

Results

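Cells of the dorsolateral and flank skin of mouse embryos were profiled by droplet-based single-cell RNA sequencing that reads the 3′ end of transcripts. The 6 libraries, each from skin pooled over embryos and sorted for cells that exclude the dye DAPI, fell into 4 groups. The controls, labelled wild type, had 2 libraries at embryonic day (E) 13.5 and 2 at E14.5. The loss-of-function (LOF) groups had 1 library per stage, so their effects within a stage have no replicates. LOF embryos carried a tamoxifen-inducible Cre recombinase driven by Pdgfra, a receptor of dermal fibroblasts, with floxed beta-catenin and the mTmG reporter, which turns from membrane Tomato to membrane GFP on recombination. Tamoxifen was given to LOF embryos at E11.5. The labels record no tamoxifen for the controls, so effects of genotype and of the drug cannot be told apart. The deposited matrices held 41594 barcodes, 6096 to 9152 per library. Total counts of unique molecular identifiers (UMIs) were 86446575 and 56453704 for E13.5 control replicates 1 and 2, 75280717 and 53461986 for E14.5 control replicates 1 and 2, 85095371 for E13.5 LOF and 83303540 for E14.5 LOF. After filters and doublet removal 38397 cells remained. Values are UMI counts per 1000000 UMIs (CPM), summed over the cells of a class in a library, as mean ± SD with n = 2 for controls. For single libraries the range in brackets is an exact 95% Poisson interval that covers counting error only.

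Beta-catenin is encoded by Ctnnb1 (chromosome 9, 120929216 to 120960507, GRCm38), which links cadherins to actin and carries canonical Wnt signals to the nucleus. In dermal cells Ctnnb1 was at 194 and 182 CPM in the E13.5 controls, 188 and 181 CPM in the E14.5 controls, 249 CPM in E13.5 LOF and 202 CPM in E14.5 LOF (log2 fold change of LOF over control 0.22, SE 0.16, adjusted p = 0.772). In keratinocytes the values were 457 and 379, 290 and 296, 284 and 256 CPM in the same order (log2 −0.40, SE 0.16, adjusted p = 0.995). Tags at the 3′ end of a transcript need not cover floxed exons, so these values do not check the deletion.

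Dermal mesenchyme-like cells, with Pdgfra, Col1a1 and Lum, were the most abundant class, at 55.2% ± 2.72 of cells in E13.5 controls and 50.7% ± 0.898 in E14.5 controls, and 46.8% in each LOF library. Keratinocyte-like cells, with Krt5, Krt14 and Epcam, held 18.7% ± 1.92 of E13.5 control cells and 33.3% ± 2.503 of E14.5 control cells, against 12.1% of E13.5 LOF and 33.2% of E14.5 LOF cells. Muscle-like cells held 6.79% ± 1.70 and 5.52% ± 0.876 in controls of the 2 stages, and 9.09% and 7.10% in the LOF libraries. Macrophage-like cells lay between 1.52% and 2.28% in every library, Schwann-like cells between 1.63% and 2.71%, and endothelial-like cells between 0.395% and 1.05%. Unnamed clusters, among them mesenchyme led by the body-region genes Pitx1 and Meox1, held 22.7% of E13.5 LOF cells against 13.6% and 9.19% in its controls, and 2.93% of E14.5 LOF cells against 2.47% and 0.0717%. Dissection and sorting set such shares too, and an exact permutation test of 2 against 2 libraries cannot give a two-sided p below 0.333, so shares are given as description.

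Libraries also differed in genes that followed neither stage nor genotype. Gm42418, a transcript that overlaps ribosomal RNA, was at 1739 and 1136 CPM in dermal cells of E14.5 control replicate 1 and E14.5 LOF, and at 54.0 to 79.2 CPM in the other 4 libraries. The linker histone gene Hist1h1b was at 763 and 542 CPM in that pair and 17.8 to 28.7 CPM elsewhere. Gstp1, a glutathione transferase gene, was at 146 and 126 CPM in replicate 2 of the E13.5 and E14.5 controls and at 22.2 to 33.9 CPM elsewhere. Pgk1, a glycolysis gene of the hypoxia and glycolysis list, was at 72.3 and 57.3 CPM in that pair and at 8.27 to 17.4 CPM elsewhere. Keratinocytes divided the same way, with Gm42418 at 2972 and 2456 CPM in the first pair and 115 to 186 CPM elsewhere. The labels name no batch. These genes put the libraries into 3 inferred batches of 2, which are E13.5 control replicate 1 with E13.5 LOF, E14.5 control replicate 1 with E14.5 LOF, and replicate 2 of both controls. Each LOF library therefore shares its batch with a control of its stage, and the stages share a batch only in replicate 2.

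The stage comparison in controls asks how dermis and epidermis change from E13.5 to E14.5, when hair follicles of the back first form. In dermal cells, 17 of 20 genes of the dermal condensate, the fibroblast cluster under each hair placode, had higher values at E14.5, and genes of hedgehog response a median log2 of 3.57. No single gene of these lists passed 0.05 over all genes, and each list had an adjusted p = 0.190 with an estimated correlation. Ptch1, the hedgehog receptor and a target of the pathway (chromosome 13, 63508328 to 63573598), was at 2.07 ± 0.463 CPM at E13.5 and 42.5 ± 18.9 CPM at E14.5 (log2 4.36, SE 0.38, adjusted p = 0.0656). Gli1, a transcription factor switched on by hedgehog signals, was at 2.76 ± 1.59 and 18.6 ± 0.981 CPM (log2 2.79, SE 0.44, adjusted p = 0.0749). Sox2, a transcription factor of dermal condensates, was at 0.134 ± 0.0840 and 7.37 ± 4.15 CPM, and the cell cycle inhibitor Cdkn1a at 7.73 ± 1.07 and 50.02 ± 10.8 CPM. The collagen VI gene Col6a3 was at 68.5 ± 19.6 and 338 ± 107 CPM, and Hmga2, a chromatin protein of growing embryonic tissue, at 405 ± 46.7 and 131 ± 26.7 CPM (log2 −1.61, SE 0.25, adjusted p = 0.0749).

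As a set the dermal condensate list rose in dermal cells (camera adjusted p = 8.00e-14, 20 members measured, median log2 1.78), a call with an adjusted p = 0.190 with an estimated correlation. No member passed 0.05 over all genes, while 12 were higher and 1 lower adjusted over the list alone, and 17 of 20 were higher in the replicate 2 batch (median 1.32). Hedgehog response genes rose as a list (adjusted p = 4.25e-12, median 3.57, within-batch median 2.90), with an adjusted p = 0.190 with an estimated correlation. Matrix genes rose as a list (adjusted p = 2.72e-09, 20 of 20 positive, 12 adjusted over the list alone, and adjusted p = 0.290 with an estimated correlation). Col1a2 was at 1754 ± 328 and 3844 ± 449 CPM and Col5a1 at a log2 of 1.63 (SE 0.33), and 18 of 20 members were higher within batch (median 0.89). Genes of the lower dermis and fascia rose (adjusted p = 0.00296, median 0.72, 4 of 10 adjusted over the list alone, and adjusted p = 0.290 with an estimated correlation). The matrix gene Dpt was at 35.6 ± 1.32 and 166 ± 10.1 CPM and Mfap5 at 16.8 ± 2.41 and 50.9 ± 3.01 CPM, but within the replicate 2 batch 5 members were higher and 5 lower (median 0.06). Stress genes rose (adjusted p = 1.27e-07, 6 of 11 adjusted over the list alone, and adjusted p = 0.404 with an estimated correlation). The immediate early gene Junb was at 107 ± 5.25 and 442 ± 148 CPM, with 10 of 11 members higher within batch (median 1.25). The list holds genes that tissue dissociation is known to induce.

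Other dermal lists did not pass between stages. FGF response genes had an adjusted p = 0.105 (median 0.48, called higher at 0.0233 with a 3-level batch), BMP response genes 0.753 (median −0.27, called lower at 0.0289 without E13.5 control replicate 2), and hypoxia and glycolysis genes 0.864, where the median was −0.04 and the mean 0.16 and the test pointed up. Wnt targets had an adjusted p = 0.596, with 2 members higher and 2 lower adjusted over the list alone. Among them Wif1, a secreted Wnt inhibitor, had a log2 of 2.09 (SE 0.33), and Notum, which inactivates Wnt ligands, a log2 of −0.91 (SE 0.24). Proliferation genes had an adjusted p = 0.953 (mean 0.11, median −0.01, test down) and fetal growth genes an adjusted p = 0.953 (mean 0.14, median 0.28, test down, within-batch median −0.10). Tendon and cartilage genes had an adjusted p = 0.463 (median −0.74) and were called lower at 0.0116 without E13.5 control replicate 2, 0.0270 without E14.5 control replicate 1, and 0.0264, 0.0279 and 0.0202 with a 3-level batch, a 2-level batch, and a 2-level batch over all 6 libraries. Haemoglobin genes, a sign of red cells or free RNA, had an adjusted p = 0.372 (median 1.84). They were called lower at 0.00226 without E13.5 control replicate 1, and higher at 0.000292 without E13.5 control replicate 2, at 9.84e-11 without E14.5 control replicate 1, and at 0.00653, 2.91e-10 and 9.18e-07 with those batch fits.

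Gene by gene, edgeR called 0 of 14070 genes between stages in dermal cells, with 2358 at an unadjusted p under 0.05 and 769 called by DESeq2 (481 up, 288 down). The edgeR count was 356 without E13.5 control replicate 1, 272 without E13.5 control replicate 2, 485 without E14.5 control replicate 1 and 3562 without E14.5 control replicate 2. A replicate block, chosen beforehand, gave 1127 (660 up, 467 down). Fits with inferred batch, chosen after the data were seen, called 1913 genes with 3 batch levels over all 6 libraries (1199 up, 714 down) and 413 with 2 levels in the controls, where E14.5 control replicate 1 is its own batch and adds nothing to the stage effect. The stage effect of the 3-level fit rests on replicate 2 of each stage, 1 library per stage, with 1 residual degree of freedom, so its counts and SE assume that these vary like the other libraries. In the 3-level fit rises included the Wnt inhibitor Sfrp5 (log2 6.33, SE 0.31, adjusted p = 0.00148), the matrix genes Clec3b (5.29, SE 0.19) and Dpt (2.41, SE 0.14), and Col6a3 (2.35, SE 0.09). Falls in the same fit included the myosin light chain gene Myl9 (−2.25, SE 0.11), the imprinted gene Nnat (−1.99, SE 0.12), Hmga2 (−1.87, SE 0.14) and the tubulin gene Tubb2b (−1.83, SE 0.09). Dermal cells of E13.5 controls lay mainly in clusters 0, 2, 3 and 6, those of E14.5 control replicate 1 in clusters 1, 9, 13 and 15, and those of E14.5 control replicate 2 in clusters 5 and 22.

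In keratinocytes the stage comparison showed stratification, the build-up of layers above the basal layer. Krt1 (chromosome 15, 101845426 to 101850794), a keratin of suprabasal cells, rose from 27.9 ± 1.44 to 827 ± 75.3 CPM (log2 4.95, SE 0.23, adjusted p = 0.00165), and its partner Krt10 from 67.1 ± 2.47 to 1356 ± 300.01 CPM (log2 4.39, SE 0.24, adjusted p = 0.00165). Ly6d, a surface protein of stratified epithelium, rose from 0.422 ± 0.118 to 65.7 ± 13.2 CPM (log2 7.29, SE 0.38, adjusted p = 0.00165), and Dmkn, a secreted protein of differentiating epidermis, from 10.8 ± 12.5 to 1132 ± 120 CPM (log2 6.78, SE 1.11, adjusted p = 0.0462). Irx6, a homeobox transcription factor, fell from 74.5 ± 3.38 to 4.12 ± 3.06 CPM (log2 −4.14, SE 0.50, adjusted p = 0.0131), and Sox11, a transcription factor of embryonic progenitors, from 133 ± 14.3 to 18.2 ± 4.64 CPM (log2 −2.79, SE 0.31, adjusted p = 0.00949).

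Other large rises by the fixed rule were Capns2 (log2 6.74), Elovl4 (6.18), which lengthens very long fatty acids of the skin barrier, Fam25c (6.11), Lgals3 (6.02), Them5 (5.85), Sbsn (5.14) and the skin protease Asprv1 (5.02), with SE of 0.36 to 0.65. The other large falls were Ucp2 (−2.15), the connexin genes Gjb2 (−2.09) and Gjb6 (−1.90), Nnat (−2.07), Igfbp2 (−1.98), the embryonic claudin gene Cldn6 (−1.92), Rasl11b (−1.72) and Ccdc102a (−1.61), with SE of 0.22 to 0.38. EdgeR called 408 of 12773 genes (319 up, 89 down) and DESeq2 844. The count was 633 without E13.5 control replicate 1 and 2807 without E14.5 control replicate 2. With a replicate block it was 1433 (981 up, 452 down), of which 407 were among the 408. With inferred batch of 3 levels over all 6 libraries, where the stage effect rests on replicate 2 alone, it was 2659, of which 393 were among the 408, and with 2 levels in the controls it was 389, of which 270 were among the 408. Keratinocytes of E13.5 controls lay mainly in clusters 7 and 14, those of E14.5 control replicate 1 in clusters 8 and 12, and those of E14.5 control replicate 2 in cluster 16. Clusters 11, 19 and 25 held cells of both E14.5 controls, with 321 and 355, 292 and 286, and 173 and 270, counted with cells called doublets.

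**Figure D1:**
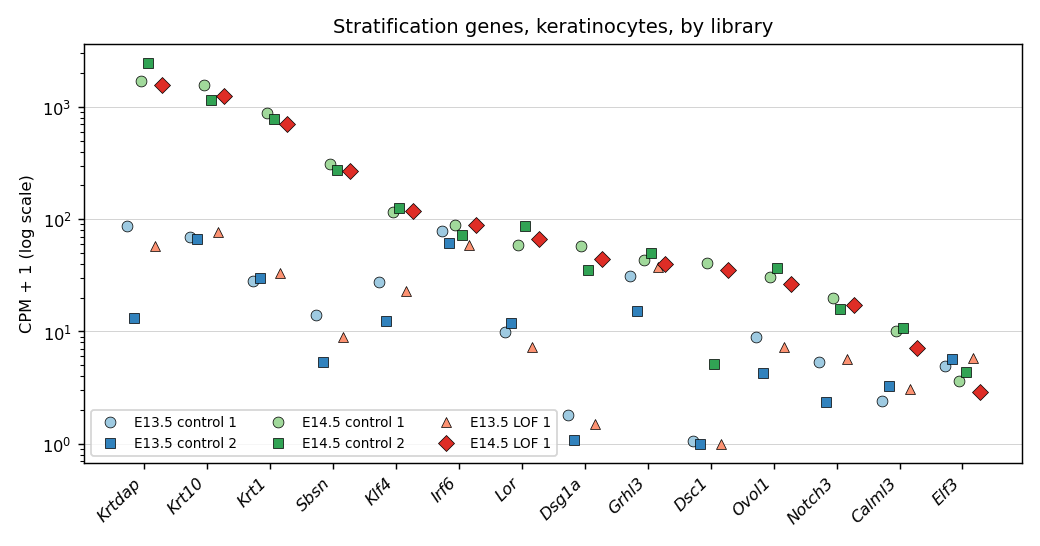
CPM of stratification genes in keratinocytes, on a log axis after adding 1, with each of the 6 libraries as a point. Krt1 lay at 26.9 to 32.1 CPM in the E13.5 libraries and at 706 to 880 CPM in the E14.5 libraries of both genotypes.

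Stratification genes rose as a list (adjusted p = 3.13e-29, median log2 2.84, 9 of 14 past 0.05 over all genes and 12 adjusted over the list alone), with an adjusted p = 0.132 with an estimated correlation, and 13 of 14 were higher within the replicate 2 batch (median 2.98). Stress genes rose (adjusted p = 5.95e-06, 2 of 12 over all genes and 9 adjusted over the list alone, and adjusted p = 0.648 with an estimated correlation). The immediate early gene Jun had a log2 of 1.89 (SE 0.34, adjusted p = 0.0398) and 11 of 12 higher within batch. Placode genes had an adjusted p = 0.194, yet 2 members rose, the hedgehog ligand Shh (log2 5.35, SE 0.67, adjusted p = 0.0135) and the homeobox gene Lhx2 (3.71, SE 0.64, adjusted p = 0.0342), both at under 4 CPM. Adjusted over the list alone, 3 placode genes were higher and 2 lower. Basal epidermis genes had an adjusted p = 0.0743 (called higher at 0.0447 without E14.5 control replicate 2), though the hemidesmosome collagen Col17a1 rose (log2 2.06, SE 0.31, adjusted p = 0.0240).

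Periderm genes had an adjusted p = 0.173, with Krt17 up (log2 1.53, SE 0.26, adjusted p = 0.0324) and Cldn6 down. They were called higher at 0.0303 without E13.5 control replicate 1, 0.0334 without E13.5 control replicate 2, and 6.37e-11 without E14.5 control replicate 1, and at 0.00480, 2.62e-07 and 1.34e-06 with a 3-level batch, a 2-level batch, and a 2-level batch over all 6 libraries. Fetal growth genes had an adjusted p = 0.927 (median and mean above 0, test down), within which Hmga2 fell (−1.54, SE 0.21, adjusted p = 0.0176) while the imprinted genes Plagl1 (1.58, SE 0.27, adjusted p = 0.0319) and H19 (1.09, SE 0.21, adjusted p = 0.0448) rose. Wnt targets had an adjusted p = 0.938 (mean 0.31, median 0.04, test down), with Wif1 alone past 0.05 (4.02, SE 0.63, adjusted p = 0.0263). Hypoxia and glycolysis genes had an adjusted p = 0.0559 (11 of 11 positive), with Ndrg1 past 0.05 (2.25, SE 0.35, adjusted p = 0.0254). They were called higher at 0.0383 without E13.5 control replicate 2, 0.0144 without E14.5 control replicate 1, and 0.000488, 0.00832 and 0.00651 with the same batch fits. Proliferation genes had an adjusted p = 0.0763 (median −0.33, called lower at 0.0190 with a 3-level batch), BMP response genes 0.938 and FGF response genes 0.938 (mean 0.07, median −0.12, test down). Haemoglobin genes had an adjusted p = 0.294 and were called higher at 5.33e-05 without E13.5 control replicate 2, 0.0144 without E14.5 control replicate 1 and 0.0392 with a 2-level batch.

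The genotype comparison asks what differs in the dermis when beta-catenin is targeted in Pdgfra-expressing fibroblasts, a loss that these data do not check. Of 11 Wnt target genes, 10 at E13.5 and 8 at E14.5 lay below both controls of the stage in LOF dermal cells. Sp5, a transcription factor and direct Wnt target (chromosome 2, 70474923 to 70477729), was at 61.5 ± 0.888 CPM in E13.5 controls and 6.11 CPM (5.30 to 7.01) in E13.5 LOF, and at 52.3 ± 3.17 and 20.7 CPM (19.1 to 22.5) at E14.5 (log2 over both stages −2.27, SE 0.48, adjusted p = 0.237). Nkd1, a feedback inhibitor of the pathway (chromosome 8, 88521354 to 88594884), was at 158 ± 20.4 CPM against 34.5 CPM (32.6 to 36.6) at E13.5 and at 172 ± 4.22 against 78.5 CPM (75.4 to 81.8) at E14.5 (log2 −1.69, SE 0.29, adjusted p = 0.233). Notum was at 28.1 ± 0.542 against 3.24 CPM and at 14.7 ± 0.257 against 5.63 CPM, and Wif1 at 24.01 ± 9.48 against 4.22 CPM and at 101 ± 26.5 against 42.5 CPM.

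The list of Wnt targets fell in LOF dermal cells (camera adjusted p = 2.97e-14, 10 of 11 members negative, median log2 −1.69), with an adjusted p = 0.134 with an estimated correlation. None of the 11 passed 0.05 over all genes, and 7 were lower adjusted over the list alone. The median over controls of the same stage was −2.16 at E13.5 and −0.89 at E14.5, both at percentile 0 of 10000 random lists matched on expression. Against the control of the same inferred batch, 11 of 11 members were lower at E13.5 (median −2.02) and 10 of 11 at E14.5 (median −1.11). In cells thinned to 3000 UMIs, Sp5 was detected in 13.7%, 14.3%, 11.6% and 14.1% of control dermal cells, against 1.30% of E13.5 LOF and 5.63% of E14.5 LOF cells. The share in macrophage-like cells, which should lack Sp5, was at most 0.781%, below their floor of 3 counts at 1.79% to 3% per library. Before thinning the dermal shares were 28.2%, 26.4%, 30.9% and 26.9% in controls and 3.00% and 10.8% in LOF, with median depths of 7116 to 10807 UMIs in dermal cells and 7760 to 15315.5 UMIs in macrophage-like cells. Within 9 of 10 dermal sub-clusters held by both genotypes, 8 to 11 of the 11 members were lower in LOF (medians −0.18 to −1.56). In the condensate-like one 5 of 11 were (median 0.03). All E13.5 medians fell short of −2.16, so mixture may play a part.

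**Figure D2:**
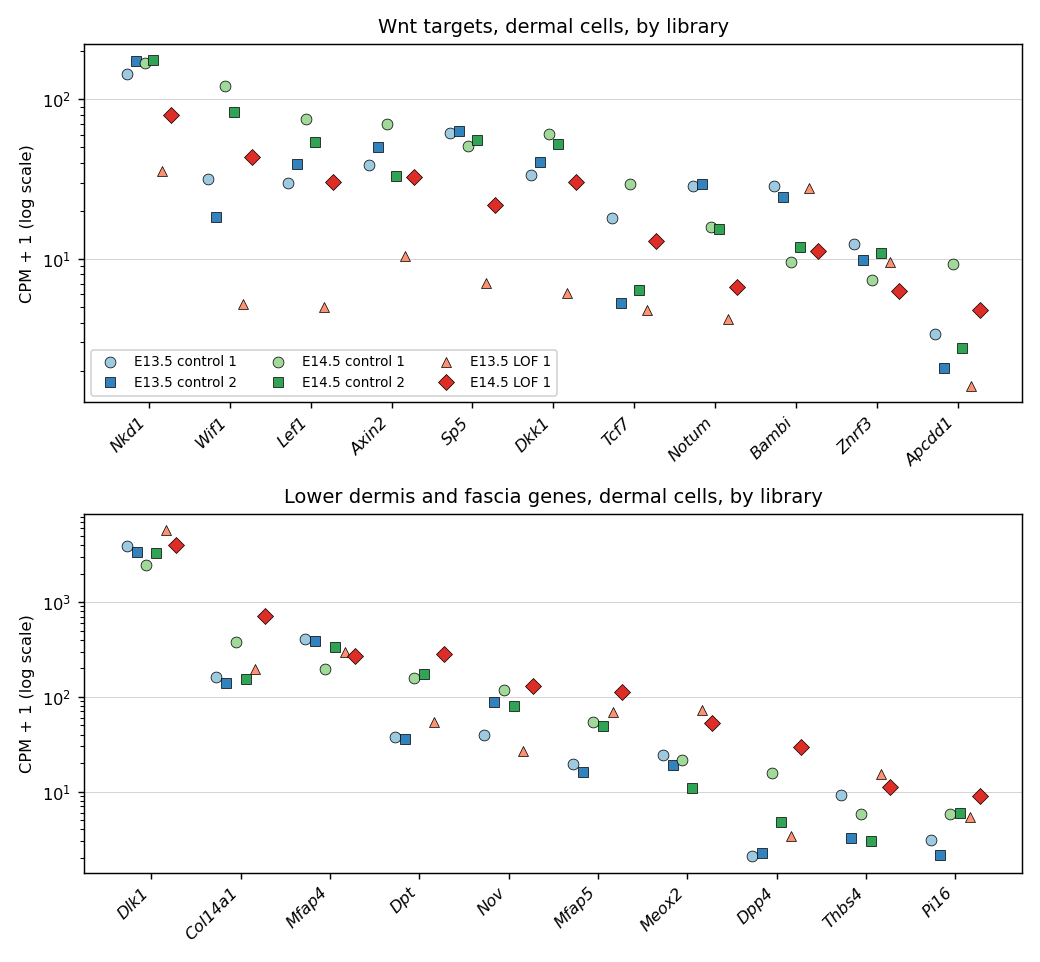
CPM in dermal cells, on a log axis after adding 1, of Wnt target genes and of genes of the lower dermis and fascia, with each of the 6 libraries as a point. Nkd1 lay at 143 to 175 CPM in the 4 controls, at 34.5 CPM in E13.5 LOF and at 78.5 CPM in E14.5 LOF.

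Genes of the lower dermis and fascia rose in LOF dermal cells (adjusted p = 1.92e-08, 8 of 10 positive, median log2 0.96, and adjusted p = 0.110 with an estimated correlation). Mfap5 was at 16.8 ± 2.41 against 68.3 CPM (65.6 to 71.2) at E13.5 and at 50.9 ± 3.01 against 111 CPM (108 to 115) at E14.5 (log2 1.55, SE 0.23, adjusted p = 0.233), and Meox2, a homeobox gene of somite-derived cells, at 20.6 ± 3.65 against 71.7 CPM and at 15.1 ± 7.49 against 51.3 CPM. Over all genes 0 members passed 0.05 by edgeR, and 6 were higher adjusted over the list alone. Within batch 8 of 10 were higher at E13.5 (median 0.63) and 10 of 10 at E14.5 (median 0.87). This list was not compared within dermal sub-clusters, so a change in the mixture of dermal cells stays open. Some body-region genes differed as well. Meox1 was at 14.1 and 5.11 CPM in E13.5 controls and 82.3 CPM in E13.5 LOF, and at 7.21 and 2.62 CPM in E14.5 controls and 34.01 CPM in E14.5 LOF. Zic1, a gene of dorsal tissue, was at 47.6 and 79.4 CPM in E13.5 controls and 7.25 CPM in E13.5 LOF, and at 49.6 and 52.9 against 32.02 CPM at E14.5. Others differed little, with Hoxc10 at 56.6 and 76.8 against 51.03 CPM at E13.5 and at 45.3 and 49.004 against 47.5 CPM at E14.5, and Tbx15 at 73.9 and 67.01 against 59.96 CPM and at 80.3 and 47.4 against 67.7 CPM. Twist2, a transcription factor of dermal fibroblasts, was at 548 and 601 against 187 CPM at E13.5 and at 664 and 841 against 375 CPM at E14.5.

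Proliferation genes fell as a list in LOF dermal cells (adjusted p = 4.99e-06, 18 of 20 negative, median −0.36, 0 members adjusted over the list alone, and adjusted p = 0.178 with an estimated correlation). Within batch 19 and 20 of 20 were lower at the 2 stages. Birc5, needed for chromosome segregation, was at 268 ± 29.8 against 188 CPM at E13.5 (183 to 192) and at 261 ± 6.79 against 146 CPM at E14.5. Tendon and cartilage genes rose (adjusted p = 0.00175, median 0.79, 1 of 8 adjusted over the list alone, and adjusted p = 0.162 with an estimated correlation). The cartilage regulator Sox9 was at 18.5 ± 7.01 against 71.4 CPM and at 20.3 ± 0.224 against 38.3 CPM, and 7 and 6 of 8 were higher within batch. Chondrocyte-like cells, a separate class with Col2a1 and Sox9, held 0.912% and 0.0872% of E13.5 control cells and 1.63% (1.33 to 1.97) of E13.5 LOF cells, and none in the E14.5 libraries, where the floors were 0.0362% to 0.0538%. Matrix genes rose (adjusted p = 0.00672, 16 of 20 positive, 0 adjusted over the list alone, and adjusted p = 0.391 with an estimated correlation). Postn had a log2 of 1.18 (SE 0.34) and Fbln1 one of −0.65 (SE 0.20). The matrix and proliferation lists were not compared within dermal sub-clusters either, so a change in cell mixture stays open for both. The matrix call was lost at 0.0650 without E14.5 LOF and 0.0777 in the 4 libraries of the larger of 2 inferred batches. Of the LOF libraries those 4 hold E13.5 LOF alone. Imprinted and other fetal growth genes rose (adjusted p = 0.0325, 3 of 10 adjusted over the list alone, and adjusted p = 0.391 with an estimated correlation). Plagl1 was at 224 ± 44.6 against 381 CPM and at 295 ± 44.7 against 532 CPM. That call was lost at 0.0596 without E13.5 control replicate 1, 0.0540 without E14.5 control replicate 2, 0.445 without E14.5 LOF, 0.0541 with a 2-level batch and 0.491 in those 4 libraries.

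Dermal condensate genes fell as a list in LOF dermal cells (adjusted p = 0.0316, 14 of 20 negative, median −0.15, and adjusted p = 0.407 with an estimated correlation), with 1 member, Inhba, lower adjusted over the list alone. Inhba, which encodes a subunit of activin, was at 54.7 ± 4.95 against 12.1 CPM (10.95 to 13.4) at E13.5 and at 37.7 ± 3.35 against 15.9 CPM (14.5 to 17.4) at E14.5. The list's median was 0.05 at E13.5 and −0.51 at E14.5, and within batch −0.02 (10 of 20 lower) and −0.53 (18 of 20 lower). The call was lost at 0.0872 without E13.5 control replicate 1 and 0.0804 without E14.5 control replicate 1, and pointed up at 0.576 without E14.5 LOF and 0.868 in the 4 libraries of the larger batch. No call was made for BMP response genes (adjusted p = 0.617), FGF response genes (0.0753), hedgehog response genes (0.178), stress genes (0.378), hypoxia and glycolysis genes (0.0687) or haemoglobin genes (0.0708). FGF response genes were called higher at 0.0301 without E14.5 control replicate 1, 0.00815 without E14.5 LOF and 0.00174 in those 4 libraries. Hedgehog response genes were called lower at 0.0180 without E13.5 control replicate 2, 0.0315 without E13.5 LOF and 0.0240 with a 3-level batch. Stress genes were called higher at 0.0286 without E14.5 control replicate 2 and 4.30e-05 without E14.5 LOF, at 0.0430 and 0.0288 with a 3-level or 2-level batch and at 9.81e-06 in those 4 libraries. They were called lower at 0.0109 without E13.5 LOF. Against the control of the same batch 12 of 12 stress genes were higher at E13.5 (median 0.96) and 5 of 12 at E14.5 (median −0.06). Hypoxia genes were called lower at 0.0402 without E14.5 control replicate 1, and haemoglobin genes lower at 0.000491, 0.0187 and 2.17e-05 without E13.5 control replicate 1, E14.5 control replicate 1 and E13.5 LOF.

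Gene by gene, edgeR called 0 of 14560 genes by genotype in dermal cells, with 1315 at an unadjusted p under 0.05 and 345 called by DESeq2 (196 up, 149 down). The edgeR count was 2 without E14.5 control replicate 1, the genes Esr1 (log2 4.65) and Ano3 (5.97), named after their values were seen. Fits with inferred batch, chosen after the data were seen, called 500 genes with 3 levels (300 up, 200 down, 217 of them also called by DESeq2) and 0 with 2 levels, where 2181 had an unadjusted p under 0.05. The 3-level fit compares each LOF library with the control of its batch and has 1 residual degree of freedom. In simulated data it made 74 false calls over 14721 genes, against 14 over 14300 for the fit without batch. Rises in the 3-level fit included the chaperone Clu (log2 1.84, SE 0.08, adjusted p = 0.00279), Gdf10 (1.28, SE 0.12), Tshz2 (1.23, SE 0.06), Clec3b (1.15, SE 0.09) and Postn (0.82, SE 0.07). Falls in that fit included Nrn1 (−1.56, SE 0.10, adjusted p = 0.00503), the fibroblast surface protein Thy1 (−1.32, SE 0.07), the Wnt feedback gene Nkd2 (−1.14, SE 0.12) and the parathyroid hormone receptor gene Pth1r (−1.08, SE 0.09). Dermal cells of E13.5 LOF lay mainly in clusters 0, 2 and 6, and those of E14.5 LOF in clusters 1, 9, 13 and 15. Counted with cells called doublets, cluster 3 held 133 cells of E13.5 LOF against 1252 and 1374 in its controls.

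The same comparison in keratinocytes, where Pdgfra was at 0.875 to 2.07 CPM, asks how the epidermis differs when beta-catenin is targeted in the dermis. In LOF keratinocytes 12 of 15 placode genes had a negative log2 fold change and 3 a positive one, none past 0.05 over all genes, and the list had an adjusted p = 0.0617 with an estimated correlation. At E13.5, 9 lay below and 4 above both controls. Dkk4, a secreted Wnt inhibitor of hair placodes (chromosome 8, 22624043 to 22627547), was at 52.5 ± 17.9 CPM in E13.5 controls and 5.87 CPM (4.58 to 7.403) in E13.5 LOF, and at 65.7 ± 19.4 against 23.5 CPM (21.7 to 25.4) at E14.5 (log2 −2.24, SE 0.48, adjusted p = 0.995). Edar, the ectodysplasin receptor that patterns placodes (chromosome 10, 58600789 to 58675654), was at 15.4 ± 1.60 against 8.43 CPM (6.88 to 10.2) and at 14.8 ± 0.905 against 9.27 CPM (8.17 to 10.5). Bmp2, a growth factor of placodes, was at 30.5 ± 5.28 against 6.03 CPM and at 25.6 ± 2.23 against 17.4 CPM. In cells thinned to 3000 UMIs, Dkk4 was detected in 7.38% and 6.59% of E13.5 control and 4.63% and 6.93% of E14.5 control keratinocytes, against 0.921% in E13.5 LOF and 2.73% in E14.5 LOF. Dermal cells, which should lack Dkk4, had at most 0.471%, with no Dkk4 in E13.5 LOF dermal cells, where the floor of 3 counts is 0.102%. Unthinned keratinocyte shares were 15.2%, 11.3%, 5.96%, 9.14%, 2.37% and 3.71% in the same order, at median depths of 9702 to 15526 UMIs in keratinocytes and 7116 to 10807 UMIs in dermal cells.

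Placode genes fell as a list (adjusted p = 2.01e-08, 12 of 15 negative, median −0.50, 2 lower adjusted over the list alone, and adjusted p = 0.0617 with an estimated correlation), with 11 and 13 of 15 lower within batch at E13.5 and E14.5. Wnt targets fell (adjusted p = 2.98e-09, 10 of 11 negative, median −0.59, 2 lower adjusted over the list alone, and adjusted p = 0.0617 with an estimated correlation), with 11 and 10 of 11 lower within batch, though Sp5 and Dkk1 were at under 3 CPM. Genes abundant in dermal cells moved with them in keratinocytes, a sign of free RNA, with Twist2 at 6.04 to 18.7 CPM in controls and 3.64 and 3.36 CPM in LOF and Crabp1 at 29.2 to 73.2 CPM in controls and 21.3 and 13.1 CPM in LOF. Lef1 and Axin2, which are abundant in keratinocytes, did not lie below the E14.5 controls in E14.5 LOF cells thinned to 3000 UMIs. Lef1 was detected in 41.3% and 43.2% of E13.5 control, 19.3% of E13.5 LOF, 37.2% and 30.3% of E14.5 control and 37.3% of E14.5 LOF keratinocytes. Axin2 was detected in 7.73%, 9.05%, 4.47%, 10.7%, 6.20% and 10.99% in the same order. Macrophage-like cells had Lef1 in at most 1.61% and Axin2 in at most 2.38%. Unthinned keratinocyte shares were 77.4%, 76.5%, 52.5%, 61.0%, 51.2% and 59.98% for Lef1 and 28.9%, 25.3%, 21.8%, 32.96%, 17.5% and 29.8% for Axin2. Median depths were 9702 to 15526 UMIs in keratinocytes and 7760 to 15315.5 UMIs in macrophage-like cells. Basal epidermis genes rose (adjusted p = 0.000392, median 0.24, 0 adjusted over the list alone, and adjusted p = 0.139 with an estimated correlation). The basal keratin Krt15 was at 620.0 ± 11.1 against 956 CPM and at 903 ± 80.2 against 1201 CPM, and 6 and 7 of 8 higher within batch. Fetal growth genes rose (adjusted p = 0.00253, 11 of 11 positive, median 0.21, 0 adjusted over the list alone, and adjusted p = 0.262 with an estimated correlation), a call lost at 0.103 without E13.5 LOF, with 10 and 5 of 11 higher within batch. Hypoxia and glycolysis genes, among them Bnip3 (log2 −0.52, SE 0.18), fell (adjusted p = 0.00253, median −0.20, 0 adjusted over the list alone, and adjusted p = 0.402 with an estimated correlation), a call lost at 0.143 without E14.5 LOF and 0.209 in the 4 libraries of the larger batch, with 8 and 10 of 11 lower within batch. Haemoglobin genes rose (adjusted p = 0.00253, 7 of 7 positive, 0 adjusted over the list alone, and adjusted p = 0.511 with an estimated correlation), with a median of 2.31 at E13.5 and −0.40 at E14.5 and within-batch medians of 3.02 and −0.15. The haemoglobin call was lost at 0.433 without E13.5 control replicate 1 and turned to lower at 0.0292 without E13.5 LOF. No member of these 6 lists passed 0.05 over all genes by edgeR.

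No call was made in keratinocytes for FGF response (adjusted p = 0.890), BMP response (0.137), stress (0.0638), stratification (0.648), periderm (0.410) or proliferation genes (0.890, mean 0.02, median −0.02, test down). Krt1 in LOF was at 32.1 CPM (28.96 to 35.4) against 27.9 ± 1.44 CPM at E13.5 and at 706 CPM (697 to 716) against 827 ± 75.3 CPM at E14.5. Stratification genes were called lower at 0.00699 without E13.5 control replicate 2 and 0.00434 with a 3-level batch. FGF response genes were called higher at 0.0243 without E14.5 LOF and 0.0140 in the 4 libraries of the larger batch. BMP response genes were called higher at 0.0465, 0.00595 and 0.00215 without E13.5 control replicate 1, E14.5 control replicate 2 and E14.5 LOF, and at 0.0117 with a 2-level batch and 0.00187 in those 4 libraries. Stress genes were called higher at 0.0334, 1.41e-15 and 4.36e-07 without E13.5 control replicate 2, E14.5 control replicate 2 and E14.5 LOF, at 4.06e-22 and 5.39e-15 with a 3-level or 2-level batch and at 9.86e-13 in those 4 libraries. Within batch 11 of 12 stress genes were higher at E13.5 (median 0.71) and 9 of 12 at E14.5 (median 0.26). Periderm genes were called lower at 0.000818 without E13.5 LOF, and higher at 0.00543 and 0.0160 without E14.5 control replicate 2 and E14.5 LOF, 0.00196 with a 2-level batch and 6.18e-06 in those 4 libraries. EdgeR called 0 of 13101 genes, with 204 at an unadjusted p under 0.05. DESeq2 called 3, all lower in LOF, which were Dkk4 (log2 −2.27), Sp5 (−3.35) and the transcription factor gene Usf1 (−2.45), named after their values were seen. Fits with inferred batch called 6 genes with 3 levels (2 up, 4 down), and 0 with 2 levels (367 at an unadjusted p under 0.05). In simulated data the 3-level fit made 39 false calls over 13174 genes, against 20 over 12846 without batch. The 6 were the immediate early genes Fos (1.19, SE 0.10, adjusted p = 0.00388) and Fosb (1.77) up, and Crabp1 (−1.14, adjusted p = 0.00267), a gene abundant in dermal cells, Usf1 (−1.94), Slc16a3 (−1.73) and the placode gene Pthlh (−1.24, adjusted p = 0.0466) down. Keratinocytes of E13.5 LOF lay mainly in clusters 7 and 14 and those of E14.5 LOF in clusters 8 and 12. Counted with cells called doublets, E14.5 LOF also had 424 in cluster 11 and 352 in cluster 19.

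Condensate-like and placode-like cells give the same comparison at the level of hair follicle primordia. A dermal condensate-like sub-cluster, with Sox2, Foxd1, Cdkn1a and Gal, held 5.34% (exact binomial 95% interval 4.56 to 6.20) and 4.50% (3.77 to 5.33) of dermal cells in the E14.5 controls and 2.35% (1.89 to 2.87) in E14.5 LOF. At E13.5 it held 0 of 3506, 0 of 3277 and 0 of 2935 dermal cells in the controls and LOF, with exact intervals up to 0.105%, 0.1125% and 0.126%. Dermal sub-clusters were almost wholly of 1 stage, so these limits bound membership of this sub-cluster and not the share of condensate-like cells at E13.5. A placode-like cluster, with Dkk4, Pthlh and Krt17 among its leading genes, held 9.21% (7.94 to 10.6) and 13.7% (12.2 to 15.3) of E14.5 control keratinocytes and 5.67% (4.84 to 6.60) of E14.5 LOF keratinocytes. At E13.5 the placode-like cluster held 1.14% and 0 of 1149 control keratinocytes, the latter allowing up to 0.3205%, and 1.05% (0.456 to 2.06) of LOF keratinocytes. Suprabasal-like cells held 10.5% and 4.00% of E13.5 control keratinocytes and 9.21% in E13.5 LOF, against 31.5% in each E14.5 control and 27.2% (25.5 to 28.9) in E14.5 LOF. With cells called doublets kept, clustering again flagged 20.8% and 4.38% of dermal cells in the E14.5 controls and 7.74% in LOF as condensate-like. LOF then lay between the controls, but the flagged groups are unlike. A sub-cluster of 942 cells led by Tex15, Slitrk6 and Sema6d was now flagged, with 2 markers among its leading genes against 4 before. It held 629 and 2 cells of the E14.5 controls and 311 of LOF, so most flagged cells of replicate 2 lay elsewhere. This shift cannot be read as an effect of doublets alone. The condensate-like, placode-like and suprabasal-like clusters are defined by genes of the lists above, so the shares are not independent of the list values.

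Single marker genes gave a less uniform picture in cells thinned to 3000 UMIs. Sox2 was detected in 2.08% (1.60 to 2.66) and 1.16% (0.794 to 1.63) of E14.5 control dermal cells and in 1.08% (0.779 to 1.47) of E14.5 LOF cells, so that LOF lay below both controls but its interval overlapped that of replicate 2. Keratinocytes of these libraries, which should lack condensates, had Sox2 in 0.320%, 0.261% and 0.221% of cells. Foxd1, a transcription factor of condensates, was detected in 4.06% and 0.942% of E14.5 control and 1.56% of E14.5 LOF dermal cells, so that LOF lay between the controls, and in at most 0.0532% of keratinocytes. Sox18 was detected in 1.11% and 0.797% of E14.5 control and 0.264% of E14.5 LOF dermal cells, and in no thinned keratinocyte, where the floor of 3 counts is 0.111% to 0.160% in these libraries. Unthinned shares in E14.5 controls and LOF were 3.39%, 2.06% and 1.65% for Sox2, 6.04%, 1.64% and 2.53% for Foxd1, and 2.32%, 1.75% and 0.645% for Sox18. Median depths were 9970, 7116 and 7557 UMIs in dermal cells and 12996.5, 9702 and 9811 UMIs in keratinocytes.

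In thinned keratinocytes Edar was detected in 5.004% and 4.57% of E13.5 control, 3.73% and 4.48% of E14.5 control, 2.63% (1.61 to 4.03) of E13.5 LOF and 2.40% (1.85 to 3.05) of E14.5 LOF cells, against 0.0264% to 0.114% of dermal cells. Unthinned Edar shares were 18.7%, 12.7%, 12.1% and 11.8% in controls and 11.7% and 8.03% in LOF. Shh was detected in 0.533% and 1.04% of E14.5 control and 0.738% of E14.5 LOF keratinocytes (unthinned 2.18%, 2.66% and 1.38%), and in no thinned dermal cell of these libraries, where the floor is 0.0793% to 0.109%. No thinned E13.5 keratinocyte had Shh, with floors for the detected share at 0.263% and 0.264% in controls and 0.395% in LOF. Median depths at E13.5 were 13917, 9971 and 15526 UMIs in keratinocytes and 9937, 7946 and 10807 UMIs in dermal cells.

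**Figure D3:**
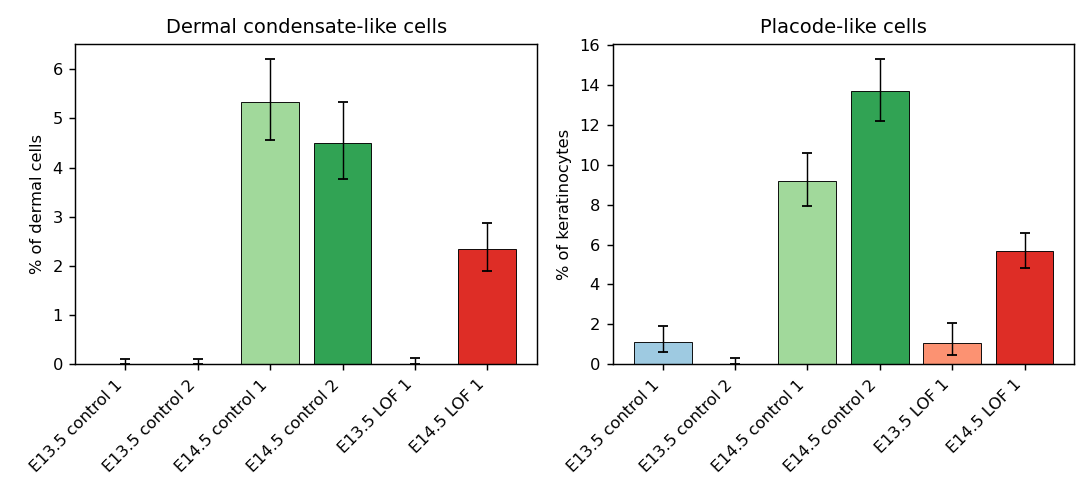
Percent of dermal cells that were condensate-like and percent of keratinocytes that were placode-like in each of the 6 libraries, with bars for the share and lines for its exact 95% binomial interval. At E14.5 the condensate-like share was 5.34% and 4.50% in controls and 2.35% in LOF.

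Among the smaller classes most genes were called between stages in muscle-like cells, whose summed depth was the highest, at 2807569 to 10711814 UMIs per control library against 272210 to 1991911 in the other 3 classes. EdgeR called 30 of 10661 genes there (22 up, 8 down; DESeq2 157), with the immediate early gene Fos (log2 3.07, SE 0.32, adjusted p = 0.0120), the cytokine inhibitor Socs3 (2.74, SE 0.40) and Chodl (2.07, SE 0.30) up, and Rprm (−3.84, SE 0.38, adjusted p = 0.0120), the neuronal tubulin gene Tubb3 (−3.32, SE 0.31) and Dusp6 (−1.93, SE 0.30) down. Muscle-like cells of the E13.5 controls and E14.5 control replicate 2 lay mainly in cluster 10, with 477, 291 and 221 cells, and those of E14.5 control replicate 1 in cluster 21, with 264 cells and 23 in cluster 10. Cells called doublets are included in these numbers. The muscle count was 53 without E13.5 control replicate 1, 303 without E14.5 control replicate 1 and 2779 without E14.5 control replicate 2. Sostdc1, an inhibitor of BMP and Wnt signals, rose in Schwann-like cells (log2 2.82, SE 0.28, adjusted p = 0.0271) as the 1 gene called of 8722 (DESeq2 8), where the count was 12, 10, 53 and 1508 without E13.5 control replicates 1 and 2 and E14.5 control replicates 1 and 2. In endothelial-like cells edgeR called 0 of 5900 genes (446 at an unadjusted p under 0.05, DESeq2 11), and 77, 4, 50 and 356 with the same libraries left out, the 4 genes being Cpa3, Fabp4, Rpl29 and Gm10709. In macrophage-like cells it called 0 of 8530 genes (654 at an unadjusted p under 0.05, DESeq2 16), and 25, 17, 132 and 1693 with the same libraries left out. By genotype edgeR called 0 genes in endothelial-like, macrophage-like, Schwann-like and muscle-like cells, with 96, 192, 153 and 133 at an unadjusted p under 0.05 and 0 called by DESeq2 in each. Without E13.5 control replicate 1 the count was 1 in endothelial-like cells (Ccl21a) and 1 in macrophage-like cells (S100a8). Without E14.5 control replicate 2 it was 3 in macrophage-like cells, the imprinted genes Cdkn1c, Dlk1 and Meg3, and 1 in Schwann-like cells (Apoe). These genes, and the 4 endothelial genes above, were named after their values were seen.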

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

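The tests of a difference between the LOF effects of the stages, of inferred batch, of body region, of eGFP-marked cells, of Esr1 and of reporter transcripts in this part were chosen after the results were seen.

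Wnt target genes were lower in dermal cells of both LOF libraries, with list medians of −2.16 at E13.5 and −0.89 at E14.5 that differed by an interaction term (camera adjusted p = 2.78e-12, and adjusted p = 0.212 with an estimated correlation), where stage and the single LOF library of each stage cannot be told apart. A difference between library batches as the whole cause was argued against, since the list was still called lower with a 3-level batch as covariate (adjusted p = 5.63e-09, in a range of 2.81e-32 to 0.134 over 11 alternatives, of which 10 made the call and the estimated correlation did not). Body region of the E13.5 LOF library was argued against as the whole cause too, since the call stood without that library (adjusted p = 2.08e-08). A fall only in dermal cells marked by eGFP was argued against, because the median in LOF cells with no eGFP UMI was at least 0.937 of that in cells with 2 or more. Dermal cells with an eGFP UMI made up 49.5% in E13.5 LOF and 59.7% in E14.5 LOF. A rate shared by all cells would give 96.4% and 88.5%. Missed detection at such a rate leaves most cells without eGFP unaccounted for, while Cre-recombined cells with little eGFP stay possible. Loss of beta-catenin, which the design names, may lower these genes, a hypothesis found and tested on the same data. The region of the E14.5 LOF library and tamoxifen, recorded for LOF alone, stay open, as does dermal cell mixture for part of the fall.

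Esr1, which encodes an estrogen receptor, was at 82.7 and 55.5 CPM in dermal cells of the E13.5 and E14.5 LOF libraries and at 2.26 to 4.43 CPM in the 4 controls, and it was singled out after its values were seen. Body region was argued against, since all 10 dermal sub-clusters of at least 50 cells in the LOF libraries had at least 38.2 CPM. Transcripts of the Cre transgene, which joins Cre to a mutated estrogen receptor, may be counted as Esr1. Classes with at least 50 CPM of Pdgfra had 18.6 CPM or more and those under 10 CPM of Pdgfra at most 5.04 CPM, but the lowest lower bound of the former (13.1) did not clear the highest upper bound of the latter (17.2, from 29 endothelial-like cells), so this stays open. A response to loss of beta-catenin stays open too. The log2 difference of Esr1 between LOF dermal cells with and without eGFP was 0.0019 (SE 0.06). By the shares above, missed detection at a shared rate does not account for most cells without eGFP. Recombined cells with little eGFP still cannot be told apart from unrecombined ones.

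Transcripts of eGFP, which no comparison used, were at 373.8 and 327.3 CPM in dermal cells of E13.5 LOF and E14.5 LOF, but also at 127.6 and 95.82 CPM in replicate 2 of the E13.5 and E14.5 controls, against 3.03 and 5.25 CPM in replicate 1. Free RNA was argued against, since dermal cells had at least 71.8 times the eGFP CPM of keratinocytes in the same library. Mislabelled LOF libraries were argued against, since dermal Esr1 in replicate 2 was at most 2.29 CPM. A reporter allele expressed with Pdgfra may be the source. Pdgfra was higher in eGFP-positive dermal cells of replicate 2 by a log2 of 0.33 (SE 0.08, adjusted p = 0.00958). A shared rate would give eGFP in 62.3% (E13.5) and 48.7% (E14.5), near the 56.5% and 46.6% found. The split is largely sampling and depth and cannot decide. Apart from the reporter allele no explanation from the embryos' genotype or biology was tested, and the controls stayed in every comparison as labelled.

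Other lists differed in their LOF effect between the E14.5 and E13.5 libraries by the same test at the preset correlation, with the effect lower at E14.5 in each, and none was called with an estimated correlation. In dermal cells these were dermal condensate (adjusted p = 6.6e-06), FGF response (0.0294), stress (1.53e-10) and haemoglobin genes (9.42e-07), with an adjusted p = 0.577 for FGF response and 0.440 for the others with an estimated correlation. In keratinocytes they were FGF response (0.00466), BMP response (0.0224), stress (9.4e-06), periderm (9.4e-06) and haemoglobin genes (1.66e-16), each with an adjusted p = 0.444 with an estimated correlation. Each effect within a stage rests on 1 LOF library, so a difference between stages cannot be told apart from a difference between those libraries. Gene by gene, edgeR called 0 of 15161 dermal and 0 of 13619 keratinocyte genes for this difference, with 210 and 105 at an unadjusted p under 0.05, and DESeq2 was not run for it.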

How the results depend on the processing

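The alternatives with inferred batch, the 4 libraries of the larger batch, cells of at least 5000 UMIs and dermal cells without the condensate-like sub-cluster were chosen after the results were seen.

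Of 3660 settings run for the 227 gene results named by rule, 3214 stayed on the same side of the threshold, 401 were newly past it and 45 no longer past it. These counts do not show whether genes that stayed short of the threshold kept their direction. For 50 list results, 525 settings gave 424 the same call, 59 new calls, 33 lost calls and 9 turned directions. Of the counts and shares, 205 stayed within their limits and 83 did not. Of 24 shares of cells with a UMI, 19 moved without thinning, which changes depth by construction. For the rest the cause was not tested.

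Dermal stage counts, 0 by edgeR with TMM, were 27 with RLE factors, 1127 with a replicate block, 1064 with all 6 libraries, 1913 with those and a 3-level batch, 292 with those and a 2-level batch, 413 with a 2-level batch in controls, 769 with DESeq2, 650 with no filter on low counts, and 272 to 3562 with 1 library left out. Epidermal stage counts, 408 in the comparison as reported, were 1433 with a replicate block, 1477 with all 6 libraries, 2659 and 931 with those and a 3-level or 2-level batch, 844 with DESeq2, 1305 with no filter and 373 to 2807 with 1 library left out. Dermal genotype counts were 1 with RLE factors (Esr1), 2 with doublets kept (Esr1, Cdh4), 2 at Leiden resolution 0.5 (Esr1, Emcn), 500 with a 3-level batch, 144 in the 4 libraries of the larger batch, 345 with DESeq2, 7 with no filter and 0 to 2 with 1 library left out, these genes being named after their values were seen. Epidermal genotype counts were 6 with a 3-level batch, 3 with DESeq2 and 0 with any library left out.

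Stage counts in endothelial-like, macrophage-like, Schwann-like and muscle-like cells were 11, 16, 8 and 157 with DESeq2 and 67, 148, 209 and 634 with no filter. With 1 library left out they were 4 to 356, 17 to 1693, 10 to 1508 and 39 to 2779. Genotype counts with no filter were 2 in macrophage-like cells (Crabp1 and Hspa1a, named after their values were seen), 6 in Schwann-like and 38 in muscle-like cells, and with 1 library left out 0 to 1, 0 to 3, 0 to 1 and 0 in the 4 classes.

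Lists called numbered 0 with an estimated correlation in all 4 comparisons. Dermal stage lists called were 8 with a 3-level batch and 5 to 8 with 1 library left out, dermal genotype lists 6 to 10 with 1 library left out, and epidermal genotype lists 6 to 9. Epidermal stage lists called were 5 with a 3-level batch, 5 with a 2-level batch, 4 with all 6 libraries and a 2-level batch, and 3 to 5 with 1 library left out. Haemoglobin genes turned to lower in the dermal stage comparison without E13.5 control replicate 1 (adjusted p = 0.00226, with 9.84e-11 to 0.672 over the left-out libraries) and in the epidermal genotype comparison without E13.5 LOF (0.0292, with 1.32e-22 to 0.433). Dermal condensate genes pointed up by genotype in the 4 libraries of the larger batch (adjusted p = 0.868) and without E14.5 LOF (0.576, with 8.12e-06 to 0.576 over the left-out libraries). Stress genes turned to lower in the dermal genotype comparison without E13.5 LOF (adjusted p = 0.0109, with 4.30e-05 to 0.753). Periderm genes turned to higher by genotype with a 2-level batch (0.00196), in the 4 libraries of the larger batch (6.18e-06), without E14.5 control replicate 2 (0.00543) and without E14.5 LOF (0.0160), with 0.000818 to 0.464 over the left-out libraries.

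Dermal shares at E14.5 were 49.2% in controls and 45.01% in LOF with doublets kept, 51.9% and 49.6% at Leiden resolution 0.5, and 49.3% in controls with cells of at least 5000 UMIs, and the E13.5 LOF share was 43.5% at resolution 0.5. With doublets kept, keratinocytes held 31.3% of E14.5 LOF, macrophage-like cells 2.70% of E14.5 controls and 2.63% of E14.5 LOF, and condensate-like cells 7.74% of E14.5 LOF dermal cells. Their share in E14.5 controls was then 12.6%, the mean of 20.8% and 4.38%, so LOF no longer lay below both controls. That clustering flagged a broader sub-cluster as condensate-like, so these shares are of unlike groups. With cells of at least 5000 UMIs condensate-like cells held 1.82% in E14.5 LOF. With 1 control library left out, dermal shares were 53.3% to 57.1% at E13.5 and 50.1% to 51.4% at E14.5, and keratinocyte shares 17.3% to 20.0% and 31.6% to 35.1%.

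A minimum of 2000 UMIs removed no cell, so that alternative says nothing about stability. Sub-cluster resolution 1 was run for condensate-like cells and could not be applied to placode-like cells, which were not sub-clustered. A replicate block assumes that equal replicate numbers share a source, which the labels do not state and the inferred batches go against for replicate 1. With 2 libraries per stage and 1 LOF library per stage, simulated changes of 2 times were called for 1 of 50 genes in the dermal stage test and 10 of 50 in the dermal genotype test, and for 40 and 43 of 50 at 4 times. Those simulated genes varied independently and had no batch difference, unlike the real libraries. A share of cells with a UMI counts detection at 3000 UMIs per cell, so a share of 0 does not bound how many cells express a gene.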

Other observations

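The tests of eGFP-positive against eGFP-negative cells in this part were chosen after the results were seen, and the shares and cluster values carry no test.

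Mast-like cells, with the proteases Cpa3, Cma1 and Tpsb2, held 0.599% of cells in E13.5 controls and 1.86% in E14.5 controls as means (n = 2 each), 0.989% in E13.5 LOF (0.759 to 1.27) and 2.46% in E14.5 LOF (2.14 to 2.82). Pericyte-like cells, which wrap small vessels and had Rgs5, Kcnj8 and Abcc9, held 0.917% and 2.11% in controls of the 2 stages and 1.20% and 2.22% in LOF. Melanoblast-like cells, the pigment cell precursors, held 0.562% and 0.627% of E13.5 control cells and 0.0319% (0.00386 to 0.115) of E13.5 LOF cells, 2 of 6269. With cells called doublets kept these shares were 0.689%, 0.730% and 0.2115% (0.116 to 0.355), as 12 of the 14 melanoblast-like cells of E13.5 LOF had been called doublets. At E14.5 they held 0.521% of control replicate 1 and 0.386% of LOF. In E14.5 control replicate 2 they held 0 of 5576 cells, where the floor of 3 counts is 0.0538%. With cells called doublets kept they held 0.393% there, so every one of the 23 had been called a doublet.

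Within dermal cells both LOF libraries differed from controls of their stage in the make-up of sub-clusters. A sub-cluster led by Hbb-y, Tbx3os1, Hba-x and Igfbp3, followed by genes such as Acta2, Aldh1a2, Lsp1 and Gdf10, held 7.10% and 3.02% of dermal cells in E13.5 controls and 45.7% in E13.5 LOF. Another, led by Hbb-y, Bex1 and Hoxc5, followed by genes such as Calb1, Nnat, Nrgn and Hmga2, held 37.1% and 44.6% in controls and 3.51% in LOF. Hbb-y and Hba-x are haemoglobin genes, a sign of red cells or free RNA. At E14.5 a sub-cluster with Postn and Dpt held 29.67% of LOF dermal cells and 16.98% of those of control replicate 1. Another, with Clec3b, Mfap5 and Dpp4, held 21.63% and 14.9%, and a proliferating sub-cluster, with Mki67 and Top2a, 14.8% and 28.15%. A sub-cluster led by Zeb2 differed less, at 31.22% and 33.62%. Control replicate 2 had at most 0.3142% of its dermal cells in any of these. Counted with cells called doublets, unnamed mesenchyme with Pitx1 and Meox1 held 598 and 39 cells of the E13.5 controls and 1405 of E13.5 LOF. An unnamed cluster with the tendon genes Scx and Tnmd, counted the same way, held 314 and 496 cells of the E13.5 controls and 26 of E13.5 LOF. At most 8 cells of any E14.5 library lay in either. Of the gene lists, only Wnt targets were compared between genotypes within dermal sub-clusters. For the lower dermis and fascia, matrix and proliferation lists, a change in cell mixture cannot be told apart from a change within cells. The same holds for the rises of Postn and Clec3b.

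Transcripts of tdTomato were at 1013 and 817 CPM in keratinocytes of E13.5 control replicates 1 and 2 and at 36.9 and 245 CPM in those of E14.5, at 986 CPM in E13.5 LOF and at 53.7 CPM in E14.5 LOF. In dermal cells they were at 2.53 to 21.9 CPM in the 6 libraries. The row was identified by its name alone, and neither its sequence nor how much of the transgene's 3′ end it covers is given, so its levels cannot be compared between stages or classes with confidence. The controls, labelled wild type, had these transcripts too, which leaves their genotype open. Transcripts of eGFP were at 353.6 and 288 CPM in pericyte-like cells of the LOF libraries and at 1.08 to 4.55 CPM in keratinocytes of all libraries.

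Dermal cells with at least 2 eGFP UMIs were compared with those with none in the same libraries. Positive cells were deeper, with medians of 9333 against 7016 and 8301 against 6521 UMIs in control replicate 2 of the 2 stages and 11090 against 10560 and 7929 against 7334 UMIs in LOF, so the calls cannot be told apart from a selection of deeper cells. With the spread shared with control replicate 2, edgeR called 2 of 13278 genes in LOF libraries (337 at an unadjusted p under 0.05), Hba-x (log2 2.90) and Wt1 (−1.46), named after their values were seen. In LOF libraries alone it called 12 of 13387 (655 at an unadjusted p under 0.05). In the shared fit the Wnt target list had an adjusted p = 0.750. Stress genes were the 1 list called there, lower in eGFP-positive cells (adjusted p = 0.0169, and adjusted p = 0.689 with an estimated correlation). In replicate 2 of the controls it called 2274 genes (1150 up, 1124 down), and 989 differed between the 2 comparisons by a test of the difference. In those controls proliferation genes were higher in eGFP-positive cells (camera adjusted p = 3.38e-19, and adjusted p = 0.174 with an estimated correlation), as were Wnt targets (0.00382, and adjusted p = 0.419 with an estimated correlation). Genes of the lower dermis and fascia (1.04e-10, and adjusted p = 0.172 with an estimated correlation) and matrix genes (1.51e-07, and adjusted p = 0.172 with an estimated correlation) were lower, as were stress genes (5.26e-07, and adjusted p = 0.316 with an estimated correlation) and fetal growth genes (0.00382, and adjusted p = 0.419 with an estimated correlation). Condensate-like cells were 1.66% (1.09 to 2.43) of eGFP-negative and 2.78% (2.09 to 3.62) of eGFP-positive dermal cells in E14.5 LOF, and 4.38% (3.41 to 5.53) and 4.02% (2.435 to 6.20) in E14.5 control replicate 2.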
